A study of Mus musculus with 4 samples.

How the data were processed

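The data were single-cell RNA counts and hashtag counts from bone marrow cells of 6 female mice carrying a tamoxifen-inducible Cre under Tppp3 and a Cre-dependent tdTomato reporter. Per the labels, 2 mice received tamoxifen on postnatal days 0 and 3, 2 received tamoxifen with rapamycin on the same days, and 2 received rapamycin alone on postnatal day 30. The last treatment is called late rapamycin here, and its mice had no tamoxifen. Cells were processed on 2 days. On each day, 1 mouse of each treatment was marked with its own hashtag antibody and the 3 mice were pooled into 1 droplet run, so that the day number serves as the replicate number. The unit of replication was the mouse, with 2 mice per treatment.

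The deposited matrices, 1 per day, hold raw counts of unique molecular identifiers (UMIs) for genes and for hashtags. The submitters' processing notes name Cell Ranger 7.0.0 and the mm10 genome, while the matrix headers name Cell Ranger 8.0.1. Neither states whether intronic reads were counted. The matrices held 25058 barcodes on day 1 and 21409 on day 2, with 113535036 and 115505329 UMIs of genes. Gene positions came from a GRCm38 annotation, in which 32158 of the 32285 gene identifiers were found. The reporter and the Cre transgene were not among the features. The hashtag table and the sample labels number the mice differently: the table gives hashtags 1 and 4 to tamoxifen with rapamycin and hashtags 2 and 5 to tamoxifen, while the labels number tamoxifen mice 1 and 4. The hashtag table was used. It names the mice of hashtags 3 and 6 controls (Ctrl). These were read as the late rapamycin mice, which the labels number 3 and 6. If the label numbers are hashtag numbers, both tamoxifen treatments are exchanged.

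Hashtag counts were transformed by centred log ratios. A hashtag was called present above the 0.999 quantile of its background, and cells with exactly 1 hashtag were used (21862 on day 1 and 18881 on day 2). Barcodes with several hashtags numbered 3007 and 2365, and those with none 189 and 163. Cells needed at least 500 genes, at least 1000 UMIs and at most 10% mitochondrial UMIs. Doublets within a mouse carry 1 hashtag, so their expected number (1473 and 1154) was removed among the cells with the highest share of known multiplets among 50 neighbours. These steps left 34428 cells. Clusters were computed in Python 3.11.15 with scanpy 1.11.5, anndata 0.12.19 and leidenalg 0.10.2. The steps used 2000 variable genes chosen within days, 30 principal components with day means removed, 15 neighbours and Leiden resolution 1.0. Cell cycle, ribosomal, mitochondrial and hashtag features and Tppp3 were left out of the variable genes. A cluster was named after a cell type when at least 50% of that type's detected markers, and at least 3, were raised at least 2-fold, and when its 10 leading genes did not belong to another type. Markers had to be seen in at least 10% of cells. The naming rule was changed once after the clusters were seen. Clusters that met no rule keep their number. Cells of a class were summed per mouse, and a class was tested when every mouse had at least 50 cells.

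Summed counts were tested with edgeR 4.0.16 (quasi-likelihood test, TMM normalisation, low-count filter by filterByExpr, two-sided) in R 4.3.3, with day as a block and treatment as the factor. The 3 treatments shared 1 estimate of the spread. P values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Log2 fold changes are edgeR's fitted values. Levels are edgeR's CPM per mouse (UMIs scaled to the summed library after TMM), given as mean ± SD, except those of Tppp3, Gt(ROSA)26Sor and the genes compared over all cells, which are CPM of the plain UMI totals. Differences within a day are of log2 CPM after adding 1. List tests used log2 CPM with a prior count of 2. DESeq2 1.42.0 was run beside edgeR. Gene lists written before the data were examined were tested with camera from limma 3.58.1 at its preset correlation of 0.01, with an estimated correlation and with fry beside it. Calls of fry are those of its directional test. Of 30 lists, 25 had at least 3 measured members in HSC-like cells. Shares of cells per class were compared by exact two-sided permutation tests between 2 and 2 mice, for which the smallest possible p is 0.333, and by edgeR on cell numbers. Intervals of shares are exact 95% Clopper-Pearson intervals, and those of Tppp3 counts are exact 95% Poisson intervals over the UMIs of the class. A count of 0 was given a floor of 3 counts. Intervals and floors cover counting error only.

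The genes named were chosen by a rule set before the data were examined. For each comparison in HSC-like cells these were Tppp3, then up to 10 genes in each direction with the largest change among those past the threshold with the same sign on both days, and up to 4 members of each list with the smallest adjusted p. Where fewer than 20 genes passed, up to 10 more with the smallest p were named as values only. Predicted gene models, antigen receptor segments and sex-linked control genes were passed over. In other classes the 5 genes with the smallest adjusted p were named.

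Alternatives were no block for day, DESeq2 in place of edgeR, DESeq2 size factors, no low-count filter, leaving out the 20 most abundant genes, leaving out each mouse in turn, stricter hashtag calls (at least 90% from 1 hashtag), and stricter cell filters (1000 genes and 5% mitochondrial UMIs). Further alternatives were removing hashtag multiplets only, Scrublet (expected rate 6%) in place of the neighbour step, Leiden resolutions 0.5 and 2.0, and equal numbers of cells and UMIs per mouse (258 cells and 593050 UMIs). The exchange of hashtag numbers and the removal of dividing cells were added after the data were seen. The tests were tested on simulated data with the means, spread and depth of the HSC-like cells. The changed genes were drawn only from those at or above the median level, and no difference between days was simulated. Recovery of less expressed genes was therefore not measured. There edgeR called 96 of 100 genes changed 2-fold and 100 of 100 changed 4-fold, with 23 false calls among 11010 genes, and it made 7 false calls in late rapamycin against tamoxifen, which was simulated with no change. DESeq2 called 64 of 100 and 100 of 100, with 2 false calls and 0 in the unchanged comparison. The S phase list was also lowered 1.5-fold there. Camera called it at the preset correlation (adjusted p = 2.46e-25) but not with an estimated correlation (adjusted p = 0.153). A list not called with an estimated correlation may therefore still have changed. Other tools were numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9, with seed 1.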

Results

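Single-cell RNA counts were compared between mice given tamoxifen soon after birth, mice given tamoxifen with rapamycin soon after birth, and mice given rapamycin alone a month after birth. Rapamycin inhibits the kinase complex mTORC1, which drives protein synthesis and growth. Tamoxifen activates the Cre recombinase that marks cells expressing Tppp3. The labels give an age of 6 weeks, although the description also speaks of isolation after 2 weeks. Each treatment had n = 2 mice, processed on 2 days. Tamoxifen mice gave 5768 and 5455 kept cells with 22797063 and 27680315 UMIs. Tamoxifen with rapamycin gave 5705 and 5564 cells with 22732051 and 28253358 UMIs. Late rapamycin gave 6366 and 5570 cells with 36961235 and 31150510 UMIs. Treatments follow the hashtag table, whose control mice were read as the late rapamycin mice. If the mouse numbers of the sample labels were hashtag numbers instead, both tamoxifen treatments would be exchanged, the first comparison below would change sign, and the other two would trade places.

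The cells formed 40 clusters. Cluster 2, with 3348 cells, was named HSC-like (hematopoietic stem cell-like), because 11 of 13 detected stem cell markers were raised in it. Its leading genes included Rora, Prkg1, Mamdc2 and Itsn1, and Itsn1 is also among the genes called between treatments. Cluster 1, with 4454 cells, had 6 of 13 stem cell markers raised and led with Sema3d, Flt3, Hlf and Vldlr, so it was left unnamed. Cluster 3 was found mainly on day 1 (90% of 2228 cells) and cluster 13 almost only on day 2 (2.5% of 1090 cells from day 1). Some named classes also joined clusters split by day. Day 1 gave 99.6% and 0.0% of the cells of erythroid progenitor-like clusters 10 and 11. It gave 98.3% and 0.6% of those of neutrophil progenitor-like clusters 14 and 26. Of 13 stem cell markers, 1 was raised in cluster 3 and 4 in cluster 13. HSC-like cells held 1647928 and 2484020 UMIs in tamoxifen, 1125090 and 1730652 in tamoxifen with rapamycin, and 720431 and 2518320 in late rapamycin.

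The share of HSC-like cells depends on the other cells captured, so it does not give the size of the stem cell compartment. It was 12.7% ± 1.70 (SD, n = 2) of kept cells in tamoxifen, 8.93% ± 0.635 in tamoxifen with rapamycin, and 7.98% ± 5.55 in late rapamycin. Tamoxifen with rapamycin lay below tamoxifen by −3.76 percentage points, −3.01 on day 1 and −4.51 on day 2 (exact permutation p = 0.333, the smallest that 2 against 2 mice allow). Late rapamycin differed from tamoxifen by −4.72 points, −7.44 on day 1 and −1.99 on day 2 (exact permutation p = 0.667). Tamoxifen with rapamycin differed from late rapamycin by 0.955 points, 4.43 on day 1 and −2.52 on day 2, so that the sign differed between days (exact permutation p = 1). Late rapamycin replicate 1 set that sign, since without it the difference was −2.97. With stricter cell filters late rapamycin differed from tamoxifen by −11.89 points (−14.6 and −9.16 on the days, exact permutation p = 0.667), and tamoxifen with rapamycin differed from late rapamycin by 9.09 points (13.9 and 4.30 on the days, exact permutation p = 0.667). By edgeR on cell numbers the HSC-like log2 differences were −0.49 (adjusted p = 0.9051), −0.80 (adjusted p = 0.4157) and 0.31 (adjusted p = 0.7937) in the same order. These p values do not show that the shares were equal. Late rapamycin minus tamoxifen was 3.25 points for the unnamed cluster 13 on day 2, against −1.99 for HSC-like cells. Tamoxifen with rapamycin minus tamoxifen was −1.805 points for cluster 13 that day, the same sign as for HSC-like cells.

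**Figure D1:**
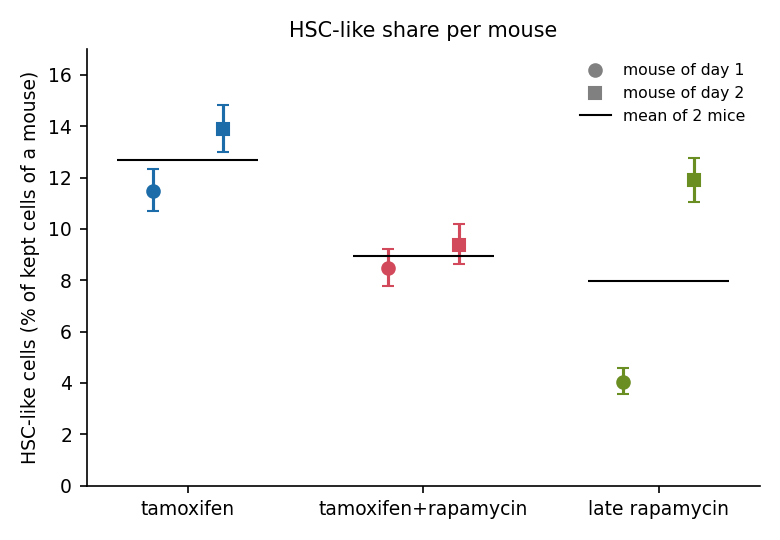
HSC-like cells as a percentage of the kept cells of each mouse, by treatment, with exact 95% Clopper-Pearson intervals, and horizontal lines at the mean of 2 mice. The tamoxifen mice lie at 11.5 and 13.9%, and the late rapamycin mice at 4.05 and 11.9%.

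Among other classes, 1 difference in cell numbers passed the threshold. B cell-like cells made up 15.4% ± 3.65 (SD, n = 2) in tamoxifen with rapamycin, 6.43% ± 6.37 in late rapamycin and 11.3% ± 3.61 in tamoxifen. Between tamoxifen with rapamycin and late rapamycin they differed by 8.94 points, 10.9 on day 1 and 7.02 on day 2 (exact permutation p = 0.333), with an edgeR log2 difference of 1.61 (adjusted p = 0.02502). Without day as a block the adjusted p was 0.7733. Late rapamycin replicate 1 had 1.93% B cell-like cells and replicate 2 had 10.9%. Without clusters 9, 25 and 28 these shares were 2.805% and 10.936%. Neutrophil-like cells were 17.4% ± 1.03 in late rapamycin against 12.1% ± 2.34 in tamoxifen and 11.6% ± 0.255 in tamoxifen with rapamycin (late rapamycin minus tamoxifen 5.28 points, 7.66 on day 1 and 2.89 on day 2, exact permutation p = 0.333). Of the 1152 such cells of late rapamycin replicate 1, 1144 belonged to cluster 9, which the other mice nearly lacked. With clusters 9, 25 and 28, found almost only in that mouse, left out, its neutrophil-like share was 0.182%, against 16.6% in replicate 2. Cluster 1 made up 9.62% ± 0.065 in late rapamycin, 14.4% ± 0.328 in tamoxifen and 15.04% ± 2.16 in tamoxifen with rapamycin. Its difference between late rapamycin and tamoxifen was −4.75 points, −4.94 on day 1 and −4.57 on day 2 (exact permutation p = 0.333). The day 1 difference depended on clusters 9, 25 and 28. Without them, cluster 1 made up 14.025% in late rapamycin replicate 1 against 14.623% in tamoxifen replicate 1. In replicate 2 these shares were 9.571% and 14.136%, so the late rapamycin mice were then no longer alike. Megakaryocyte progenitor-like cells, the precursors of platelet-forming cells, made up 1.33% ± 0.086 in tamoxifen, 1.72% ± 0.735 in tamoxifen with rapamycin and 1.09% ± 0.281 in late rapamycin. Between both tamoxifen treatments they differed by 0.398 points, 0.857 on day 1 and −0.061 on day 2 (exact permutation p = 1).

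Tppp3, which drives the Cre of this strain, was nearly undetected. HSC-like cells held 13 UMIs of it in all 6 mice, and 83 UMIs were found over all cells, of which monocyte-like cells held 28, the most of any class. The HSC-like level was 1.21 and 2.01 CPM in the tamoxifen mice, 0.889 and 1.73 in tamoxifen with rapamycin, and 1.39 and 0.397 in late rapamycin. The exact Poisson intervals overlapped, running from 0.654 to 4.70 CPM in tamoxifen replicate 2 and from 0.0101 to 2.21 in late rapamycin replicate 2. The low-count filter removed the gene, so a difference in Tppp3 was not detectable at this depth. B cell-like cells, which should lack it, held 0 UMIs of Tppp3, which allows up to 1.30 CPM in the deepest of those mice.

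The comparison of tamoxifen with rapamycin against tamoxifen asks what mTORC1 inhibition during labelling changes in stem cells. Of 11010 genes tested in HSC-like cells, edgeR called 6, of which 5 were higher and 1 lower with rapamycin. At an unadjusted p under 0.05 there were 651 genes, where chance alone gives 550, and DESeq2 called 3. On simulated data edgeR made 23 false calls in this comparison, in which other genes had been changed, so single genes at these adjusted p values are open to error. Nxpe5, which encodes a secreted or membrane protein of unknown function, rose most (log2 fold change 2.98 ± 0.237 SE, adjusted p = 0.0003539), from 9.27 ± 1.90 to 75.0 ± 3.8 CPM (SD, n = 2), with 3.04 on day 1 and 2.76 on day 2. Ctse, the aspartic protease cathepsin E, rose by 1.05 ± 0.111 (adjusted p = 0.003918), from 84.8 ± 8.76 to 176.5 ± 9.75 CPM, with 1.10 and 1.002 on the days. Sema3d, a secreted guidance factor, rose from 26.4 ± 11.9 to 74.6 ± 3.07 CPM (1.58 ± 0.213, adjusted p = 0.02485), and Plac8, which is expressed in myeloid and lymphoid progenitors, from 254.7 ± 22.5 to 425.9 ± 20.02 CPM (0.75 ± 0.094, adjusted p = 0.01684). Of the 5 higher genes 4 are described here, and the lower gene was a predicted gene model. DESeq2 did not call Sema3d (adjusted p = 0.1588). Without tamoxifen+rapamycin replicate 2, Nxpe5 was the 1 of these genes still called, while the adjusted p was 0.1037 for Ctse and 0.5498 for both Plac8 and Sema3d. The number of calls was 41 without tamoxifen replicate 1, 70 without tamoxifen replicate 2, 66 without late rapamycin replicate 1, 62 without late rapamycin replicate 2 and 11 without tamoxifen+rapamycin replicate 1.

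On GRCm38, Nxpe5 (ENSMUSG00000047592) lies on chromosome 5 from 138225898 to 138253363 and Sema3d (ENSMUSG00000040254) on chromosome 5 from 12383385 to 12588948. Ctse (ENSMUSG00000004552) lies on chromosome 1 from 131638306 to 131675505, and Plac8 (ENSMUSG00000029322) on chromosome 5 from 100553725 to 100572245. Genes short of the threshold had these fitted log2 values: Sox6 1.03 (adjusted p = 0.06937), Abca1 1.13 (adjusted p = 0.07358), Dynll1 −0.69 and Ifi204 −3.59 (adjusted p = 0.08176 each), Itsn1 −0.65 (adjusted p = 0.1006), Apoe 0.54 and Rplp0 −0.42 (adjusted p = 0.1263 each).

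**Figure D2:**
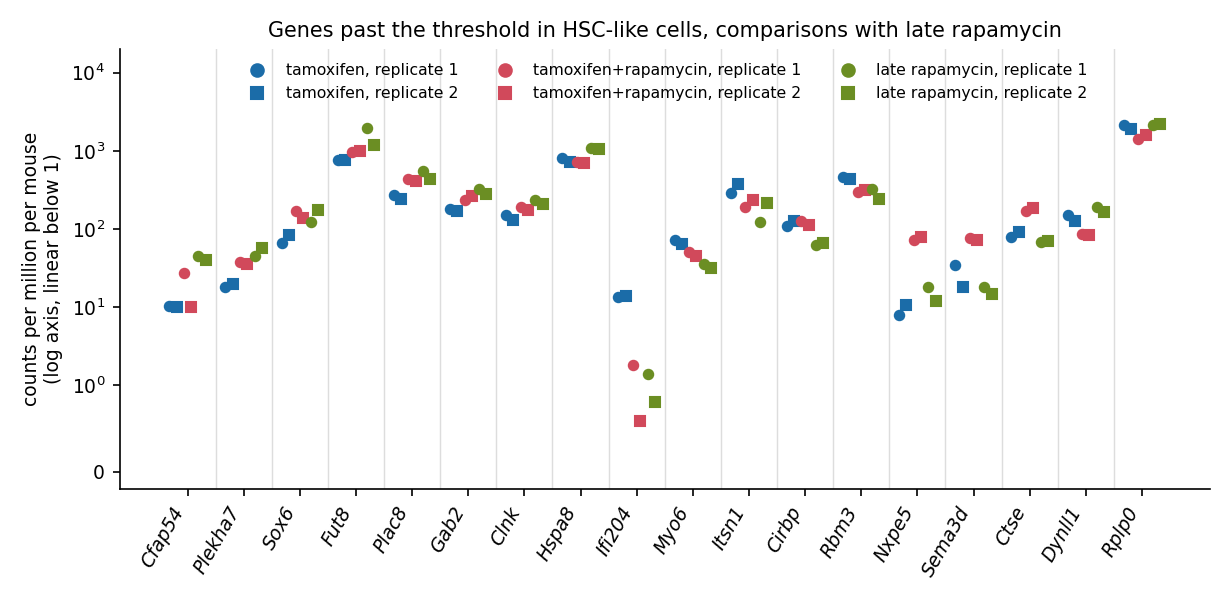
CPM of each mouse for the 18 named genes past the threshold in a comparison of HSC-like cells with late rapamycin, on a log axis that is linear below 1. Circles are mice of day 1 and squares mice of day 2, and Nxpe5 lies at 72.3 and 77.7 CPM in tamoxifen with rapamycin against 7.93 and 10.6 in tamoxifen.

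At the preset correlation camera called 6 of 25 lists in this comparison, each with adjusted p = 0.9703 with an estimated correlation, and fry called 0. Fry's mixed test takes changes in either direction. Its unadjusted p was 0.00027 for lymphoid priming, 0.0049 for oestrogen response and 0.0062 for interferon response. For cytosolic ribosomal proteins, S phase and MHC class II it was 0.178, 0.274 and 0.540. DNA replication genes of the S phase list were lower (36 of 42 below 0, median −0.24, adjusted p = 1.702e-05), with medians of −0.39 on day 1 and −0.06 on day 2. They included Cdca7 at −0.44, Uhrf1 at −0.78 and Casp8ap2 at −0.49, none of them past the threshold. The interferon response list was higher (20 of 29 above 0, median 0.18, days 0.06 and 0.18, adjusted p = 0.01812), with Rsad2 at 1.21 and Gbp2 at 0.42, and 1 gene was called adjusted over the list alone. At adjusted p = 0.04952 each, lymphoid priming was higher (7 of 10 above 0), MHC class II was higher (7 of 8 above 0, median 0.26, H2-Ab1 at 0.80), oestrogen response was lower (8 of 11 below 0, median −0.14, Xbp1 at −0.60), and cytosolic ribosomal proteins were lower (75 of 82 below 0, median −0.05). Like MHC class II, the B cell-like share was higher here, by 4.02 and 4.08 points on the days, and RNA from other cells in HSC-like droplets was not measured. These lists at 0.04952 were lost with DESeq2 size factors (adjusted p = 0.05142) and without the block (adjusted p = 0.05325). The S phase call was lost without tamoxifen replicate 1 (adjusted p = 0.5401), and the interferon call without tamoxifen replicate 2 (adjusted p = 0.688), tamoxifen+rapamycin replicate 1 (adjusted p = 0.1231) or tamoxifen+rapamycin replicate 2 (adjusted p = 0.08778). In HSC-like cells without a UMI of 10 division genes the calls of interferon response (adjusted p = 0.218), MHC class II (adjusted p = 0.112) and lymphoid priming (adjusted p = 0.442) were lost too. There camera still called S phase lower, with 34 members measured (adjusted p = 1.14e-06, and 0.852 with an estimated correlation).

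The platelet-biased HSC list, of 18 genes tied to stem cells that favour platelet production, was not called in this comparison (13 of 18 below 0, median −0.11, days −0.00 and −0.25, adjusted p = 0.7369), and none of its members was called adjusted over the list alone. Its members included Vwf at 0.77, Pf4 at −1.18 and F2r at −0.60. Fry's mixed test gave the list an unadjusted p = 0.0075, so changes of its members in both directions are not excluded. Of the lists tied to mTORC1, cytosolic ribosomal proteins were called lower, as given above. Camera did not call the others, with adjusted p = 0.8794 for translation factors with TOP messages, 0.955 for mTOR pathway components, 0.6123 for cholesterol synthesis, 0.4227 for glycolysis, 0.5045 for ATF4 targets and 0.4635 for lysosome and autophagy. These are RNA levels, taken at 6 weeks by the labels after injections on postnatal days 0 and 3. They do not measure mTORC1 activity at dosing. HSC identity was at adjusted p = 0.955, with a median of 0.06 and a mean just below 0, and quiescence at 0.955, where camera's direction was up while its median was −0.05. The lowest adjusted p among the lists not called was 0.1681, for oxidative phosphorylation.

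The comparison of late rapamycin against tamoxifen sets mice without Cre activation, treated later, against mice labelled at birth, so that tamoxifen, rapamycin and its timing differ together. Here edgeR called 14 of 11010 genes in HSC-like cells, 8 higher and 6 lower in late rapamycin, with 845 at an unadjusted p under 0.05 where chance gives 550, and DESeq2 called 3. On simulated data in which this comparison had no change, edgeR made 7 calls and DESeq2 0. Plac8 rose most firmly (0.92 ± 0.095, adjusted p = 0.002905), from 254.7 ± 22.5 to 487.1 ± 81.1 CPM (SD, n = 2), with 1.01 on day 1 and 0.84 on day 2. The transcription factor gene Sox6 rose from 73.6 ± 11.9 to 147.4 ± 36.7 CPM (1.04 ± 0.168), and the chaperone gene Hspa8 from 753.3 ± 61.5 to 1065 ± 31.7 CPM (0.50 ± 0.078), both at adjusted p = 0.03976. The RNA-binding proteins Cirbp and Rbm3, which cells make more of in mild cold, fell. Cirbp fell by 0.86 ± 0.136 on the log2 scale, from 116.3 ± 11.02 to 63.7 ± 3.16 CPM, with −0.81 and −0.90 on the days (adjusted p = 0.03976). Rbm3 fell by 0.71 ± 0.114, from 452.4 ± 19.8 to 284.7 ± 59.3 CPM, with −0.51 and −0.85 on the days (adjusted p = 0.03976). Also higher were the cilium gene Cfap54 (2.08 ± 0.304), the junction gene Plekha7 (1.481 ± 0.204), the core fucosyltransferase gene Fut8 (0.99 ± 0.146, with 1.36 on day 1 and 0.61 on day 2), and the signalling adaptors Gab2 (0.76 ± 0.114) and Clnk (0.65 ± 0.1). Also lower were the interferon-inducible Ifi204 (−3.74 ± 0.618, adjusted p = 0.04731), the motor gene Myo6 (−1.04 ± 0.167) and the endocytic scaffold gene Itsn1 (−0.94 ± 0.12, adjusted p = 0.01868).

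Hspa8 (ENSMUSG00000015656) lies on chromosome 9 from 40800984 to 40810087, Cirbp (ENSMUSG00000045193) on chromosome 10 from 80165985 to 80172786, and Rbm3 (ENSMUSG00000031167) on chromosome X from 8138975 to 8145880. Sox6 (ENSMUSG00000051910) lies on chromosome 7 from 115470872 to 116038796 and Plekha7 (ENSMUSG00000045659) beside it from 116123485 to 116308376. Cfap54 (ENSMUSG00000020014) lies on chromosome 10 from 92775619 to 93081618, and Ifi204 (ENSMUSG00000073489) on chromosome 1 from 173747293 to 173766943. Fut8 (ENSMUSG00000021065) lies on chromosome 12 from 77238125 to 77476338, Gab2 (ENSMUSG00000004508) on chromosome 7 from 97081586 to 97308946, and Clnk (ENSMUSG00000039315) on chromosome 5 from 38706462 to 38876812. Myo6 (ENSMUSG00000033577) lies on chromosome 9 from 80165031 to 80311729, and Itsn1 (ENSMUSG00000022957) on chromosome 16 from 91729281 to 91920597.

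Several of these calls were lost when 1 mouse was left out, although each such fit left 1 mouse in a treatment. Without late rapamycin replicate 2 edgeR called 153 genes, of which 8 were among the 14, and without tamoxifen replicate 2 it called 112, of which 11 were. The number was 68 without tamoxifen replicate 1, 56 without late rapamycin replicate 1 and 24 without tamoxifen+rapamycin replicate 1. Cirbp was lost without tamoxifen replicate 2 (adjusted p = 0.07695) or late rapamycin replicate 2 (adjusted p = 0.05661). Without late rapamycin replicate 2 Sox6 (adjusted p = 0.2145), Plekha7 (adjusted p = 0.09123) and Cfap54 (adjusted p = 0.05765) were lost. Ifi204 was lost without tamoxifen replicate 2 (adjusted p = 0.5134), late rapamycin replicate 2 (adjusted p = 0.2145) or tamoxifen+rapamycin replicate 2 (adjusted p = 0.08947). Without tamoxifen+rapamycin replicate 2, Myo6 (adjusted p = 0.07346), Clnk (0.07547), Rbm3 (0.07069) and Hspa8 (0.1161) were lost, and Hspa8 was also lost without tamoxifen replicate 2 (adjusted p = 0.07295) or tamoxifen+rapamycin replicate 1 (adjusted p = 0.06673). DESeq2 kept 3 of the 14, and its adjusted p was 0.591 for Cirbp 0.09986 for Rbm3, Hspa8, Sox6, Cfap54 and Gab2, and 1 for Myo6. Without day as a block Clnk (adjusted p = 0.0626), Hspa8 and Itsn1 (0.09939 each) were lost. No gene of these changed sign without the block, with DESeq2 or its size factors, with stricter hashtag calls or with 1 mouse left out. Signs were not checked under the other alternatives.

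Camera called 3 lists between late rapamycin and tamoxifen, each with adjusted p = 0.9308 with an estimated correlation, and fry called 0. Mitotic genes of the G2M phase list were higher (43 of 45 above 0, median 0.58, days 0.38 and 0.63, adjusted p = 1.303e-16), and 17 were called higher adjusted over the list alone. In HSC-like cells without division UMIs, where 24 members were measured, the list was not called (adjusted p = 0.781). Those cells were chosen for lacking UMIs of division genes, so this loss says nothing about the call of the list. Its members included Top2a at 0.67, Mki67 at 0.98 and Ube2c at 1.95, none past the threshold over all genes. The share of HSC-like cells with a UMI of any of 10 division genes, after thinning each cell to 2000 UMIs, was 29.5% and 18.3% in tamoxifen, 23.3% and 17.5% in tamoxifen with rapamycin, and 25.5% and 21.3% in late rapamycin. The B cell-like share differed between these treatments by −6.84 points on day 1 and −2.94 on day 2. RNA from other cells in HSC-like droplets was not measured. MHC class II, whose member Cd74 was also a leading gene of B cell-like cluster 8, was lower in HSC-like cells (8 of 8 below 0, median −0.30, days −0.82 and −0.14, adjusted p = 0.0001853), with Cd74 at −0.89 and H2-Aa at −1.20, and 2 members were called lower adjusted over the list alone. That call was lost without late rapamycin replicate 1 (adjusted p = 0.127), but not in HSC-like cells without division UMIs (adjusted p = 0.0231). Oxidative phosphorylation was higher (66 of 75 above 0, median 0.13, days 0.08 and 0.17, adjusted p = 0.000514), and was lost without tamoxifen replicate 2 (adjusted p = 0.4303) or late rapamycin replicate 2 (adjusted p = 0.2756), and in HSC-like cells without division UMIs (adjusted p = 0.274). The platelet-biased HSC list was not called (14 of 18 below 0, median −0.17, days 0.01 and −0.28, adjusted p = 0.1683), although adjusted over the list alone 1 member was higher and 2 were lower. Mmrn1 was at −0.74 and Selp at 1.73. HSC identity was not called (adjusted p = 0.7378, median −0.20, mean 0.01), yet 4 members were higher and 5 lower adjusted over the list alone, with Angpt1 at −0.58 and Slamf1 at 1.10. S phase was at adjusted p = 0.1979 and interferon response at 0.8234.

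The comparison of tamoxifen with rapamycin against late rapamycin sets rapamycin on postnatal days 0 and 3 against rapamycin on postnatal day 30. Only the former mice had tamoxifen. The number of injections differs too, as does the time from drug to isolation if all mice were taken at 6 weeks. An effect of the age at rapamycin cannot be told apart from these. Here edgeR called 8 genes in HSC-like cells, 4 higher and 4 lower in tamoxifen with rapamycin, with 1214 at an unadjusted p under 0.05 where chance gives 550, and DESeq2 called 7. Nxpe5 (2.47 ± 0.241, adjusted p = 0.001612), Ctse (1.36 ± 0.122, adjusted p = 0.001329) and Sema3d (2.17 ± 0.248, adjusted p = 0.004245) rose here too, from 15.1 ± 4.36, 69.3 ± 1.33 and 16.5 ± 2.38 CPM (SD, n = 2) in late rapamycin. Dynll1, a dynein light chain gene, fell by 1.07 ± 0.119 on the log2 scale (adjusted p = 0.004245), from 179.0 ± 19.3 to 84.5 ± 3.00 CPM, with −1.15 and −0.997 on the days. Hspa8 fell by 0.58 ± 0.079 (adjusted p = 0.01645), with −0.60 and −0.56 on the days. The ribosomal stalk gene Rplp0 fell by 0.54 ± 0.079 (adjusted p = 0.02794), from 2180 ± 77.9 to 1501 ± 100.2 CPM, with −0.57 and −0.51 on the days. The remaining 2 genes were predicted gene models. Dynll1 (ENSMUSG00000009013) lies on chromosome 5 from 115297110 to 115300999 and Rplp0 (ENSMUSG00000067274) on the same chromosome from 115559467 to 115563727. Without tamoxifen+rapamycin replicate 2 the calls of Nxpe5 (adjusted p = 0.06579), Sema3d (0.1031), Hspa8 (0.2239) and Rplp0 (0.1594) were lost. Without tamoxifen+rapamycin replicate 1 those of Hspa8 (adjusted p = 0.4095) and Rplp0 (0.6015) were lost, and Rplp0 was lost without the block (adjusted p = 0.05406). The number of calls was 210 without tamoxifen replicate 1, 211 without tamoxifen replicate 2, 103 without late rapamycin replicate 1 and 160 without late rapamycin replicate 2. Cirbp was at 0.86, short of the threshold.

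Camera called 5 lists in this comparison, each with adjusted p = 0.9168 with an estimated correlation, and fry called 0. G2M phase was lower with tamoxifen and rapamycin (40 of 45 below 0, median −0.60, days −0.62 and −0.63, adjusted p = 1.355e-16), and 25 members were lower adjusted over the list alone. S phase was lower (38 of 42 below 0, median −0.33, days −0.28 and −0.39, adjusted p = 1.043e-06), with Cdca7 at −0.81 and Nasp at −0.90 and 13 members lower adjusted over the list alone. Without late rapamycin replicate 2 the S phase list was not called (adjusted p = 0.1427). In HSC-like cells without division UMIs, where 34 members were measured, S phase was lower at adjusted p = 3.41e-07, and at adjusted p = 0.855 with an estimated correlation. In those cells G2M phase (adjusted p = 0.0686, 24 members) and lymphoid priming (adjusted p = 0.176) were not called, while MHC class II (adjusted p = 5.3e-05) and oxidative phosphorylation (adjusted p = 0.0061) were. The loss of G2M phase says nothing about its call, as the cells were chosen for lacking division UMIs. MHC class II was higher (8 of 8 above 0, median 0.59, days 1.26 and 0.44, adjusted p = 3.685e-06), with H2-Aa at 1.47 and Cd74 at 1.01, and 6 members were higher adjusted over the list alone. The B cell-like share was higher too, by 10.9 and 7.02 points on the days, and RNA from other cells in HSC-like droplets was not measured. Oxidative phosphorylation was lower (64 of 75 below 0, median −0.18, days −0.20 and −0.14, adjusted p = 6.01e-06). Lymphoid priming was higher (9 of 10 above 0, median 0.20, adjusted p = 0.01527), but was lost when any 1 of the 6 mice was left out (adjusted p from 0.05144 to 0.212). The platelet-biased HSC list was not called (adjusted p = 0.4469), and its median of −0.02 had the opposite sign from its mean of 0.06 and from camera's direction, which was up. Cytosolic ribosomal proteins were at adjusted p = 0.09529 (70 of 82 below 0, median −0.06).

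In the other classes edgeR called more genes, summed over classes: 196 for tamoxifen with rapamycin against tamoxifen, 548 for late rapamycin against tamoxifen, and 449 for tamoxifen with rapamycin against late rapamycin. DESeq2 called 44, 83 and 92, and edgeR without the day block called 42, 86 and 87. Erythroid progenitor-like cells had 85, 181 and 56 calls in that order (DESeq2 25, 48 and 24), and cluster 7, an Apoe and Gata2 expressing cluster, had 35, 89 and 122 (DESeq2 1, 3 and 3). Leaving out 1 mouse left its treatment with 1 mouse, which then adds nothing to the estimate of the spread. The numbers of calls moved strongly, also in comparisons that the left-out mouse was not part of. They therefore do not measure the weight of a single mouse. Without tamoxifen replicate 1 late rapamycin against tamoxifen had 198, and without tamoxifen+rapamycin replicate 2 it had 839. Tamoxifen with rapamycin against late rapamycin had 196 without tamoxifen+rapamycin replicate 1 and 683 without tamoxifen replicate 2. In neutrophil-like cells edgeR called 0 genes in each comparison, with 127, 589 and 415 at an unadjusted p under 0.05 where chance gives 422, and DESeq2 called 0, 3 and 3. In neutrophil progenitor-like cells edgeR also called 0, with 126, 532 and 536 at that unadjusted p where chance gives 487, and DESeq2 called 1, 6 and 2. The 127 and 126 of tamoxifen with rapamycin against tamoxifen lie far below chance. The 0 calls there do not show that nothing changed. In B cell-like cells edgeR called 0 for late rapamycin against tamoxifen (447 at that unadjusted p where chance gives 484, DESeq2 0).

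In B cell-like cells with tamoxifen and rapamycin, Trib2, a pseudokinase gene of developing lymphocytes, fell by 2.49 ± 0.169 on the log2 scale against tamoxifen (adjusted p = 6.683e-06) and the proton channel gene Hvcn1 by 1.94. This class pools 5 clusters whose mix differed between these mice: cluster 8, of mature B cell genes such as Ms4a1, held 122 of 506 and 361 of 757 B cell-like cells in tamoxifen, against 95 of 730 and 315 of 999 with tamoxifen and rapamycin. A change of this mix and a change within a stage were not separated. Lymphoid-primed progenitor-like cells had higher Blnk (2.04, adjusted p = 0.001013), an adaptor of the B cell receptor, and higher Dntt (0.58, adjusted p = 0.03103) in that comparison. Against tamoxifen, their late rapamycin counterparts had higher Il7r (1.484, adjusted p = 0.00293) and Blnk (1.64). In cluster 1 Nxpe5 rose by 2.38 (adjusted p = 0.009261) with tamoxifen and rapamycin, and the iron sensor gene Tfr2 fell by 2.05. Megakaryocyte progenitor-like cells of late rapamycin mice had higher chaperone genes than tamoxifen mice: Dnaja1 (1.02, adjusted p = 0.002789), Hspa8 (0.76), Hsph1 (1.47) and Hsp90aa1 (0.63). In erythroid progenitor-like cells Rbm3 fell by 0.70 (adjusted p = 1.755e-05) and the xylosyltransferase gene Xylt1 by 2.26 (adjusted p = 4.147e-08) in late rapamycin against tamoxifen, while Plekha7 rose by 2.98 (adjusted p = 1.38e-07). With tamoxifen and rapamycin, the translation initiation factor gene Eif3j2 rose by 3.86 in these cells (adjusted p = 4.06e-06).

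Lists were tested in the other classes too, and no camera call there passed with an estimated correlation. The platelet-biased HSC list was lower in late rapamycin than in tamoxifen in cluster 1 (adjusted p = 0.006802, and adjusted p = 0.8083 with an estimated correlation) and in cluster 3 (0.0383, and 0.659). In cluster 4, a dividing cluster, it was lower with either rapamycin treatment than with tamoxifen (0.02802 and 0.009396, and adjusted p = 0.9304 and 0.6469 with an estimated correlation). Cholesterol synthesis genes, which mTORC1 raises through SREBP, were higher with tamoxifen and rapamycin than with tamoxifen in neutrophil-like cells (adjusted p = 7.153e-09, and adjusted p = 0.9034 with an estimated correlation) and in monocyte-like cells (0.0001544, and 0.5938). Ribosomal proteins were lower in erythroid progenitor-like cells of both rapamycin treatments against tamoxifen (9.288e-10 and 4.261e-11, and adjusted p = 0.8441 and 0.7347 with an estimated correlation).

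**Figure D3:**
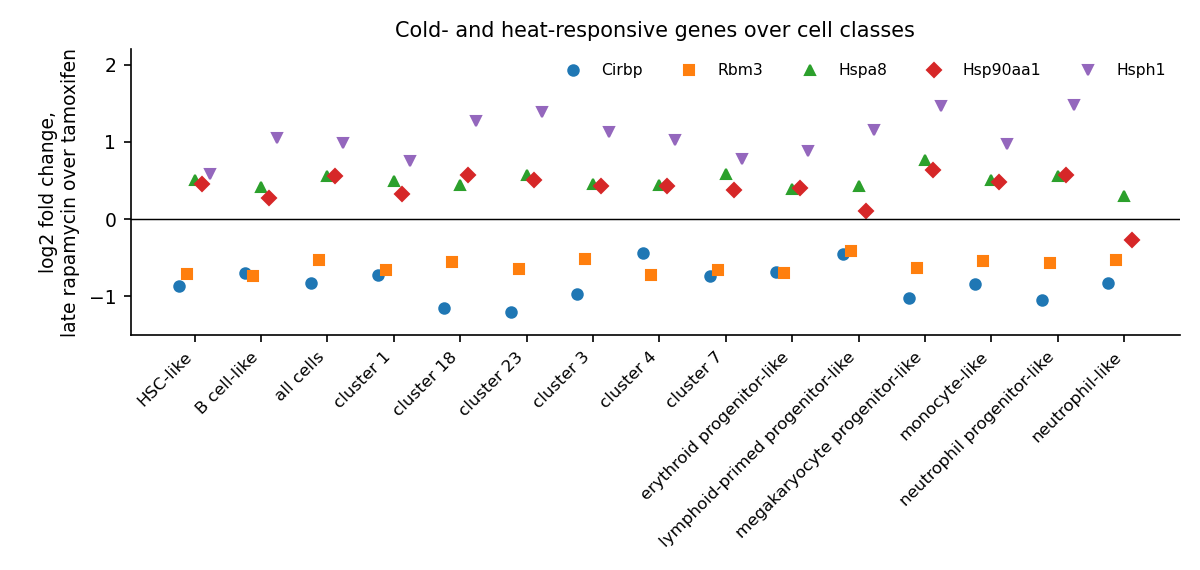
Fitted log2 fold change of late rapamycin over tamoxifen for Cirbp, Rbm3, Hspa8, Hsp90aa1 and Hsph1 in the 14 tested classes and in all cells together. Cirbp and Rbm3 lie below 0 in each of the 14 classes and Hspa8 above 0 in each, while Hsp90aa1 lies below 0 in neutrophil-like cells.

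Neutrophil-like and monocyte-like cells differed between single mice. Clusters 9, 25 and 28, which are neutrophil-like, neutrophil progenitor-like and monocyte-like, held 2002 cells, of which 1981 came from late rapamycin replicate 1. They made up 31.1% of that mouse's kept cells. Neutrophil-like cluster 5, in contrast, held 2 cells of that mouse against 248 to 328 of each other mouse.

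**Figure D4:**
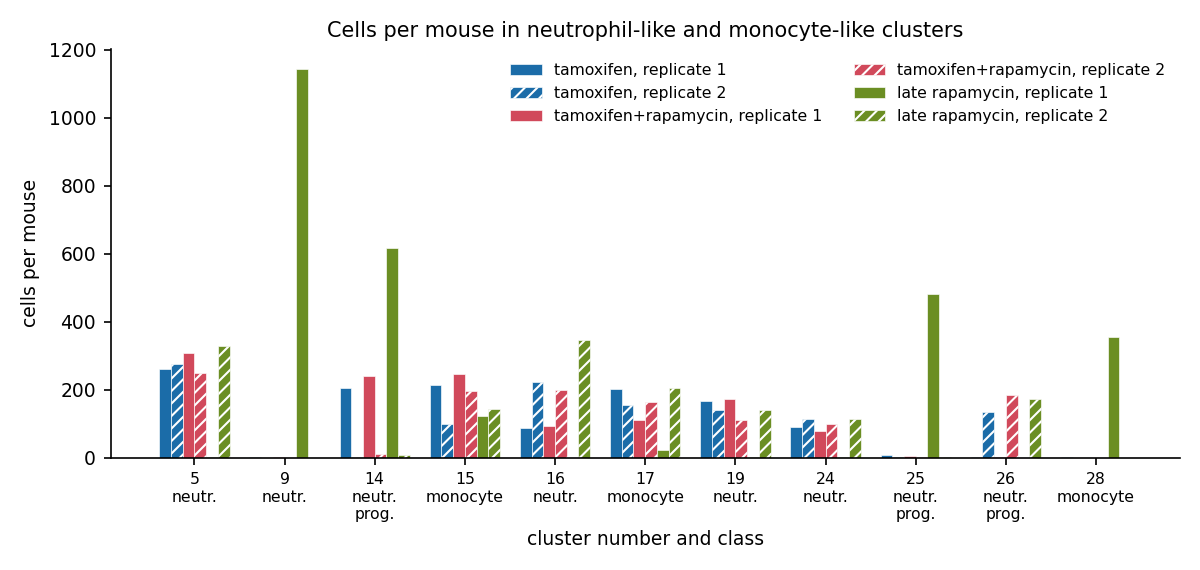
Number of cells of each mouse in each neutrophil-like, neutrophil progenitor-like and monocyte-like cluster, with plain bars for day 1 and hatched bars for day 2. Of the 2002 cells of clusters 9, 25 and 28, 1981 came from late rapamycin replicate 1.

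The non-coding transcript of the Rosa26 locus, Gt(ROSA)26Sor, lies on chromosome 6 from 113067428 to 113077333 and is the usual site of Cre reporters, although the labels give no site for this one. Gt(ROSA)26Sor was singled out after its values were seen. In megakaryocyte progenitor-like cells it was higher in late rapamycin than in tamoxifen (log2 fold change 3.11, adjusted p = 0.04062). In erythroid progenitor-like cells it was at 0.825 and 31.1 CPM in the tamoxifen mice, 57.5 and 61.3 with tamoxifen and rapamycin, and 63.9 and 68.1 in late rapamycin. In HSC-like cells it was at 3.64 and 12.9, 16.0 and 17.9, and 34.7 and 22.6 CPM in the same order.

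**Figure D5:**
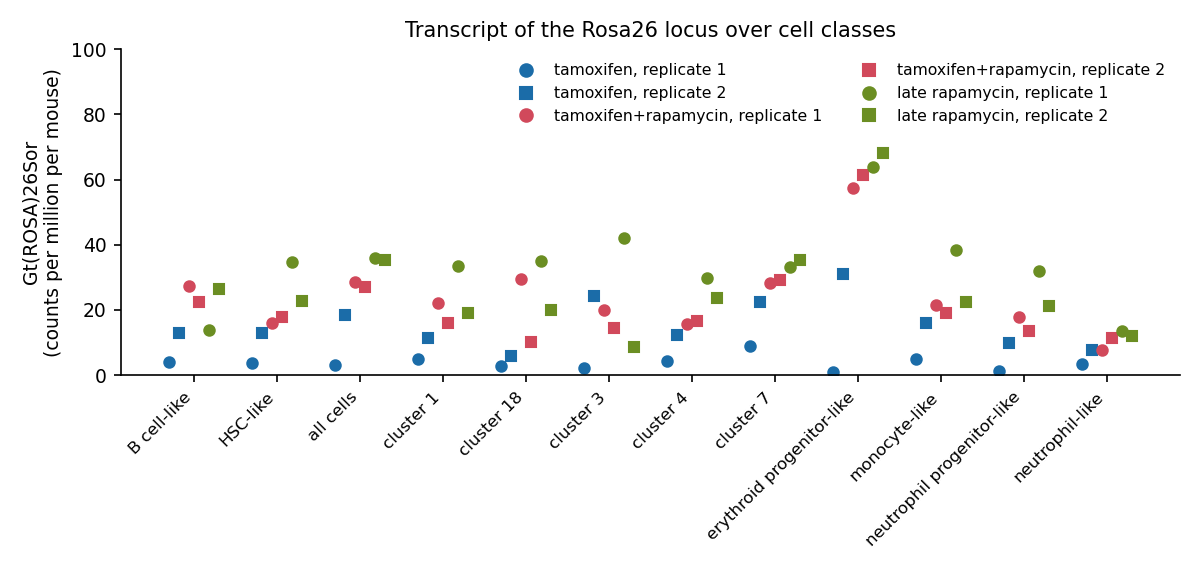
Gt(ROSA)26Sor in CPM of each mouse, with circles for day 1 and squares for day 2, in the classes with at least 100 UMIs of it and in all cells together. Tamoxifen replicate 1 is lowest in each class shown, for example at 0.825 CPM in erythroid progenitor-like cells.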

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

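Whether a treatment acted differently in another class than in HSC-like cells was tested only for genes already called in HSC-like cells, so these tests were chosen after those calls were seen. Of 288 combinations of a gene, a class and a comparison, 1 passed. Plekha7, the junction gene that rose in HSC-like cells of late rapamycin mice against tamoxifen (log2 fold change 1.481), had a larger fitted change in neutrophil progenitor-like cells, and the 2 effects differed by −3.749 (limma, adjusted p = 0.01961). The fitted size of that difference is no bound, because 1 group is at 0, and edgeR called 0 genes in neutrophil progenitor-like cells in this comparison (smallest adjusted p = 0.7439, 532 genes at an unadjusted p under 0.05, DESeq2 6), so the change of Plekha7 did not pass there. Its log2 fold change was also above the HSC-like one in erythroid progenitor-like cells (2.98), monocyte-like cells (4.25) and cluster 1 (2.58), and of opposite sign in lymphoid-primed progenitor-like cells (−0.27), the only 1 of 11 classes with that sign. None of these differences from HSC-like cells passed (adjusted p = 0.05442, 0.1445, 0.1445 and 0.1445). In neutrophil progenitor-like cells both tamoxifen mice held 0 UMIs of Plekha7, while the tamoxifen+rapamycin mice held 27 and 28 (14.3 and 13.4 CPM) and the late rapamycin mice 161 and 56 (16.5 and 29.0 CPM). Both rapamycin treatments therefore differed from tamoxifen in the same direction in these cells. In HSC-like cells Plekha7 was present in each mouse, at 17.7 and 19.6 CPM in tamoxifen, 37.5 and 35.6 with tamoxifen and rapamycin, and 44.7 and 57.1 in late rapamycin. No explanation of the difference between both classes was tested.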

How the results depend on the processing

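Tests added after the data were seen are the exchange of hashtag numbers and the HSC-like cells without division UMIs. In HSC-like cells edgeR called 6, 14 and 8 genes (tamoxifen+rapamycin against tamoxifen, late rapamycin against tamoxifen, tamoxifen+rapamycin against late rapamycin). No filter on low counts gave 78, 150 and 226, and removing hashtag multiplets only 10, 25 and 15. Scrublet gave 18, 25 and 27. Stricter cell filters gave 23 in the first and 34 in the third. DESeq2 gave 3 in the first and in the second. Leaving out the paired day block gave 10 in the first. Resolution 0.5 gave 4 and resolution 2.0 gave 9 in the second. Equal cells and depth gave 26 in the second and 44 in the third. HSC-like cells without division UMIs gave 23, 26 and 33. With DESeq2 size factors, or without the 20 most abundant genes, the same 6, 14 and 8 genes were called. If hashtag numbers were the labels' mouse numbers, the first comparison would be reversed with 6 genes (1 higher), the others would have 8 and 14, and the HSC-like share would differ by 3.76 points in place of −3.76, as both treatments trade places by construction. Leaving out 1 mouse at a time, where a treatment with 1 mouse left is assumed to vary like the others, gave 6 to 70, 13 to 153 and 11 to 211 genes. Without tamoxifen replicates 1 or 2 the first comparison had 41 and 70, without late rapamycin replicates 1 or 2 it had 66 and 62, and without tamoxifen+rapamycin replicate 1 it had 11. The second had 68, 112, 56 and 153 without tamoxifen replicates 1 or 2 or late rapamycin replicates 1 or 2, and 24 without tamoxifen+rapamycin replicate 1. The third had 210, 211, 103 and 160 without the same 4 mice. The numbers moved also in comparisons that the left-out mouse was not part of, so they do not measure the weight of a single mouse. Apart from the exchange, the cause of these changes was not tested.

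In the other classes the counts of 196, 548 and 449 fell to 42, 86 and 87 with no replicate block and to 44, 83 and 92 with DESeq2. Leaving out 1 mouse gave 143 to 2174, 198 to 11626 and 196 to 11893, the highest of each without late rapamycin replicate 2. Of the 6, 3 and 5 lists called in HSC-like cells, 0, 0 and 0 were called with an estimated correlation and 0, 0 and 0 with fry. In the first comparison no replicate block, DESeq2 size factors and stricter hashtag calls gave 2 each, and no filter on low counts gave 3. Leaving out 1 mouse gave 1 to 4 lists in the first comparison, lowest without tamoxifen+rapamycin replicate 1, and 3 to 5 in the second, highest without tamoxifen replicate 1, tamoxifen replicate 2 or late rapamycin replicate 1. The 13 UMIs of Tppp3 in HSC-like cells became 8 to 12, with 8 without tamoxifen replicate 2. Leaving out 1 mouse, the HSC-like share of tamoxifen+rapamycin minus late rapamycin ranged from −2.97 (without late rapamycin replicate 1) to 4.88 points (without late rapamycin replicate 2), while stricter cell filters gave 9.09. Late rapamycin minus tamoxifen was −11.89 points with stricter cell filters and ranged from −8.64 (without late rapamycin replicate 2) to −0.792 (without late rapamycin replicate 1) when 1 mouse was left out. Both differences from tamoxifen kept their sign in each alternative, except that of tamoxifen+rapamycin under the exchange. The cause was not tested. Named genes were followed only under no block, DESeq2, its size factors, stricter hashtag calls and leaving out 1 mouse. Of the named genes' values under alternatives, 394 kept direction and side of the threshold, 103 became called and 42 were lost, with no change of sign. For lists 90 did so and 78 were lost. With 2 mice per treatment exact tests of shares cannot pass 0.333, and with 720431 UMIs in the shallowest mouse a gene such as Tppp3 is out of reach.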

Other observations

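Tests chosen only after their results were seen are the recurrence of changes over classes, the maturation mix, both tests of the Rosa26 locus, the share of single-mouse clusters held by other mice, the number of doublets, the handling genes, the share of Rbm3 alone kept in non-dividing cells, and the removal of dividing cells as an alternative. The tests of neighbouring genes, hashtag purity, cytokine-induced genes, chaperones and the share kept in non-dividing cells were written before their results were seen, but after the patterns were.

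Genes that were present in some mice and nearly absent in others were counted over all cells: 21 genes had at least 3 CPM in the mice with expression and a difference of at least 10-fold. Of these, 12 were high in late rapamycin replicate 1 alone. Among the other 9, 4 followed a treatment, and 5 were low in 1 mouse or in another set of mice. Ifi202b, an interferon-inducible gene near Ifi204 on chromosome 1, was at 7.85 and 4.48 CPM in the tamoxifen mice and at most 0.088 in the other 4. Zfp990 was at 0.939 CPM in tamoxifen replicate 2 and at 21.1 or more in the others, and Mst1r at 0.106 in tamoxifen+rapamycin replicate 2 against 4.58 or more in the others. Of the 15 ways to split 6 mice 2 against 4, 3 follow a treatment.

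Genes that differed between treatments in HSC-like cells often differed alike in unrelated cells. Over the 28 calls, the median in 13 other classes was 0.79 of the HSC-like log2 fold change, and 20 calls had the same sign in each class tested. Ctse was higher with tamoxifen and rapamycin than with tamoxifen in 13 of 13 other classes. In cluster 1, with another mix of stem and progenitor cells, the median was 0.849, but 0.697 for tamoxifen with rapamycin against tamoxifen, and Sema3d, a leading gene of cluster 1, kept 0.424 and 0.46. Another mix of maturation stages within the HSC-like cluster cannot be told apart by this, as cluster 1 of the same mice could shift alike. The 164 genes called in 2 or more classes formed 33 pairs within 1 Mb of each other, against a median of 22 in 1000 random draws of as many genes, of which a share of 0.041 reached that number and the highest had 50. Sox6 and Plekha7 were such neighbours, as were Dynll1 and Rplp0. A candidate explanation is that mice of a treatment share a litter or chromosome segments of another strain, which would give more neighbouring pairs. The recurrence over classes cannot decide this. It restates the pattern, and a treatment effect common to all cells would give it too. The neighbour test was close to its limit, and genes near each other can also be regulated together.

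Mice may also differ in the number of Rosa26 alleles with an insertion. With both alleles in tamoxifen replicate 1, a single allele in tamoxifen replicate 2 and none in the others, the locus transcript would be nearly absent in the first and about halved in the second. Over 11 classes the median ratio to the mice of the other treatments was 0.176 in tamoxifen replicate 1 (0.013 to 0.297) and 0.571 in tamoxifen replicate 2 (0.248 to 1.131). The ratios came out near that, but the reference includes the late rapamycin mice, which were higher than tamoxifen with rapamycin in most classes. Against tamoxifen with rapamycin alone, tamoxifen replicate 2 lay nearer in HSC-like cells (12.9 against 16.0 and 17.9 CPM) than in erythroid progenitor-like cells (31.1 against 57.5 and 61.3). The labels also give all 6 mice the reporter, so the other 4 would carry no insertion at Rosa26 only if the reporter lies elsewhere or the labels are wrong. The explanation stays open. Genes within 10 Mb of Gt(ROSA)26Sor were called in any class in 6 of 99 cases (6.06%), against 579 of 12826 elsewhere (4.51%, one-sided Fisher's exact p = 0.291), so a segment of another strain around Rosa26 cannot be told apart from none with so few genes there. A biological effect of the treatments on these genes stays open as well, and with 2 mice per treatment it is confounded with any shared litter.

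The 2002 cells of clusters 9, 25 and 28 came almost only from late rapamycin replicate 1, whose cells were scarce in the usual neutrophil clusters. Over all cells, this mouse had 34.1 CPM of the acute-phase gene Saa3, against at most 0.88 in the others, and 4.82 CPM of Nos2, against 0 in the others. Doublets within this mouse would have to be few, since 1473 were expected in all 3 mice of the run and as many cells had been removed, whereas 1981 cells of these clusters came from this mouse alone. The median share of the highest hashtag was 97.96% both in these clusters and in the mouse's other cells, a difference of 0 points. That does not decide whether cells were assigned to the wrong mouse, because cells were kept for carrying a single hashtag. The other mice of the droplet run held 0.85% of these cells, and the other late rapamycin mouse held 0.05%. The clusters were picked for coming almost only from 1 mouse, so these shares restate that choice and test nothing further. An effect of the run, the day or late rapamycin would have to act on this mouse alone to give such clusters. The median of 14 cytokine-induced genes in HSC-like cells was higher in this mouse than in the others of its day by 0.569 on the log2 scale, against at most 0.179 in any other mouse. Tamoxifen replicate 1, a mouse of the same day and so part of that reference, was at −0.636. The 0.569 may therefore partly reflect a low level in that mouse. Among tested classes, erythroid progenitor-like cells, at −0.269, were the exception. An inflammation or infection of late rapamycin replicate 1 may underlie the clusters, though these values do not settle it. The late rapamycin means of shares and levels include this mouse.

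Cirbp and Rbm3 fell and Hspa8 rose in late rapamycin HSC-like cells against tamoxifen, and the signs held in each of the 14 tested classes, with medians of −0.84, −0.64 and 0.47. Longer handling cannot be told apart from none: the median of the immediate early and dissociation stress genes was 0.407 on day 1 and −0.441 on day 2, and over both days 6 members were above 0 and 10 below. A higher body or sample temperature may explain the pattern: 16 chaperone genes not seen before had median differences of 0.134 on day 1 and 0.325 on day 2. In HSC-like cells without division UMIs Rbm3 kept 1.032 of its change and was still called (−0.73 ± 0.128 SE, adjusted p = 0.00627), which argues against more dividing cells as its cause. For Cirbp (−0.70 ± 0.157, adjusted p = 0.05777) and Hspa8 (0.39 ± 0.093, adjusted p = 0.1012) division cannot be told apart from other causes, as the median kept over the 3 genes was 0.807 (median SE 0.182). An effect of the drugs stays open and untested.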
